A study of Mus musculus with 8 samples.

How the data were processed

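Gene expression was measured on 8 cryosections of mouse lung with Visium, an array of barcoded spots on which the messenger RNA of the overlying tissue is captured and counted with unique molecular identifiers (UMIs). The sections came from lungs on day 0, day 14 and day 35 after injury with bleomycin, a drug that causes lung inflammation and scarring, with 2, 3 and 3 sections. Nothing in the labels states that the sections of a day came from separate mice. The p-values therefore measure the spread between these sections, which may be technical.

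The deposited matrices hold raw UMI counts per gene and spot, made with Space Ranger 2.0.0 per the file headers. The submitters' processing notes also name STAR 2.5.1b, Cell Ranger, Seurat and the mouse genome build mm10, without a role or order for each. Every matrix covered the same 32285 genes, and 78 symbols that are shared by several gene identifiers were told apart by identifier. Coordinates in the text come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. Of the gene identifiers, 32158 were found in the reference name table, and 31436 of these carried the same symbol. How reads that fit several near-identical genes were counted is not given in the sources used here, so haemoglobin, immunoglobulin and MHC class II genes may share reads with related genes.

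Only spots over tissue were used, and no other filter was put on spots. Section totals ran from 769687 UMIs (day 14 replicate 1) to 3755022 UMIs (day 14 replicate 3). A gene with 3 UMIs, the floor used here, corresponds to 3.90 UMIs per 1e6 UMIs (CPM) in the shallowest section and 0.799 CPM in the deepest. This floor covers counting error only. Spots were not clustered and no cell types were assigned to them, since a spot can hold several cells. Cell type names below refer to fixed lists of marker genes.

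For the comparisons of days, counts were summed over the tissue spots of each section and tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, the default filter on low counts, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. All 8 sections entered one model with day as the only term, because day 0 has 2 sections. The log2 scale is used for fold changes. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic. CPM values of single genes are TMM-scaled, while CPM summed over a gene list and the floor are per total UMIs of the section without that scaling. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, over the 43 lists with at least 3 tested genes. The same test with a correlation estimated from the data and the rotation test fry were run beside it. DESeq2 1.42.0 was the alternative count test.

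Collagen was scored as the sum of Col1a1, Col1a2 and Col3a1 UMIs in a neighbourhood, which is a spot with its at most 6 adjacent tissue spots. For the share of collagen-high neighbourhoods, each was thinned to 1000 UMIs, shallower ones were left out, and the threshold was the mean over the day 0 sections of their 95th percentile, which came to 2 UMIs. Shares per section were compared with two-sided exact permutation tests. Within each section, the 25% of spots with the highest and the 25% with the lowest collagen share of neighbourhood UMIs were summed as collagen-high and collagen-low classes. These were tested with edgeR in a model with section as a block and a class effect per day, and the 3 scoring genes were left out of all counts of calls. The change of the class effect between days was tested as an interaction.

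The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, per comparison, genes past the threshold with an average log2 CPM of at least 4 and no overlap between groups (up to 8 per direction), up to 3 members of a discussed list with the smallest p, and 10 genes chosen beforehand: Col1a1, Col1a2, Col3a1, Fn1, Spp1, Timp1, Cthrc1, Sftpc, Ager and Scgb1a1. Of the genes this allowed, those in the text are a selection. For the classes, the rule took the 8 highest and 8 lowest genes past the threshold that changed the same way in every section of that day.

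Alternatives covered normalization, the count test, the low-count filter, spot depth, the genes in the library size, the sections in the fit, the replicate number as a block, the last digit of the file label (1 for the day 14 sections and day 0 replicate 1, 2 for the others) as a possible slide, thinning, and each section left out in turn. Chosen after seeing the data were the fits without Scgb1a1, without spots rich in squamous and skeletal muscle markers, and without both sections that hold such spots, as well as the squamous and proximal airway lists. A first threshold for those spots took nearly every spot, and it was replaced by 3% of neighbourhood UMIs.

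The tests were run on simulated counts with 200 changed genes, of which 100 were changed 4-fold. At 4-fold, 65% were recovered for day 14 against day 0, 49% for day 35 against day 0 and 83% for day 35 against day 14. At 2-fold the shares were 4%, 0% and 7%. In simulated collagen classes at day 14, 90% of 2-fold and 100% of 4-fold changes were recovered. The changed genes were drawn only from genes above a minimum mean count. Counts followed a negative binomial model with the dispersions estimated from the data. These shares therefore do not give the power over all tested genes or in the real sections. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.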

Results

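Spatial transcriptomes were compared between uninjured mouse lung (day 0, n = 2 sections) and lung on day 14 (n = 3) and day 35 (n = 3) after bleomycin. Tissue covered 2086 and 2848 spots at day 0, 2831, 2775 and 3464 spots at day 14, and 3048, 2013 and 2436 spots at day 35. The median UMI count per spot was 664.5 and 554 at day 0, 179, 570 and 780.5 at day 14, and 539, 511 and 593.5 at day 35. Day 14 replicate 1 was the shallowest section, with 1564 spots under 200 UMIs. Scgb1a1, the main secretory protein of club cells, took 24.0% and 27.5% of UMIs at day 0, 2.92%, 11.4% and 6.83% at day 14, and 26.6%, 16.1% and 17.5% at day 35.

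Transcripts of squamous epithelium (such as Krt13 and Krt4) and skeletal muscle were abundant in day 0 replicate 2 (5757 and 5606 CPM) and day 14 replicate 1 (12087 and 9013 CPM). In the other sections the squamous list summed to at most 59.5 CPM and the skeletal muscle list to at most 86.3 CPM. Spots with over 3% of neighbourhood UMIs from these markers numbered 112 and 278 in those 2 sections and 0 elsewhere. They held 34.0% and 55.2% of the marker UMIs of these sections. In the remaining spots of both sections the median share of neighbourhood UMIs from the markers was still 0.841% and 1.18%. Fits without marker-rich spots therefore leave part of these transcripts in.

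The first comparison asked how the lung on day 14 after injury differed from the uninjured lung. Matrix, proliferation and macrophage transcripts were at a higher level, and contractile, airway secretory and resident fibroblast transcripts at a lower one. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), stood at 1021 ± 262 CPM (SD, n = 3) against 160 ± 0.537 (n = 2), a log2 fold change of 2.68 (SE 0.61). Spp1, which encodes osteopontin (chromosome 5, 104435111 to 104441053), stood at 1740 ± 590 against 105 ± 9.49 CPM (log2 fold change 4.05, SE 0.72). The fibronectin gene Fn1 stood at 2005 ± 251 against 211 ± 53.7 CPM (log2 fold change 3.25, SE 0.80), and Scgb1a1 at 63441 ± 40231 against 279026 ± 39158 CPM (log2 fold change -2.14, SE 0.53).

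No single gene passed the threshold in this comparison: edgeR called 0 of 13260 genes, with a smallest adjusted p of 0.111 and 1558 genes at an unadjusted p under 0.05, while DESeq2 called 266. Spp1 and Col1a1 had adjusted p-values of 0.111 and 0.171 in edgeR. Groups did not overlap for 31.7% of genes, against 20% by chance. The edgeR count became 83 without day 35 replicate 2 and 25 without day 35 replicate 3, which enter the estimate of the spread.

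Fibrillar collagens and interstitial matrix rose as a list (median log2 fold change 1.71, camera adjusted p = 4.54e-14, adjusted p = 0.203 with an estimated correlation). Of its 23 measured members 13 were higher and 0 lower when adjusted over the list alone, and 0 passed over all genes. Tenascin C, Tnc, stood at 226 ± 40.4 against 17.4 ± 8.67 CPM, thrombospondin 1, Thbs1, at 260 ± 19.0 against 98.1 ± 10.0 CPM, and fibrillin 1, Fbn1, at 272 ± 51.3 against 57.5 ± 1.06 CPM. Collagen processing and matrix remodelling also rose (13 of 21 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.55e-07, adjusted p = 0.203 with an estimated correlation). Its members Timp1, a metalloproteinase inhibitor, and Lox, which crosslinks collagen, had log2 fold changes of 3.80 (SE 0.69) and 1.89 (SE 0.44), and Loxl3 of 1.77 (SE 0.41). Activated fibroblast markers rose (6 of 7 adjusted over the list alone, median 3.42, camera adjusted p = 9.59e-07, adjusted p = 0.203 with an estimated correlation), among them Cthrc1 at 45.1 ± 15.0 against 4.16 ± 2.27 CPM and Ltbp2 at 521 ± 202 against 94.9 ± 39.4 CPM.

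Cell cycle genes rose (13 of 17 adjusted over the list alone, median 1.82, camera adjusted p = 4.54e-14, adjusted p = 0.161 with an estimated correlation). Birc5, Cdk1 and Ube2c, which act in mitosis, had log2 fold changes of 3.27 (SE 0.47), 3.09 (SE 0.47) and 2.92 (SE 0.48). Monocyte-derived macrophage markers rose (10 of 12 adjusted over the list alone, median 2.79, camera adjusted p = 9.19e-12, adjusted p = 0.203 with an estimated correlation), with Trem2 at 79.9 ± 33.6 against 5.51 ± 0.888 CPM and Ms4a7 at 49.5 ± 21.6 against 3.85 ± 1.06 CPM. MHC class II genes, which present antigen, rose (6 of 8 adjusted over the list alone, camera adjusted p = 5.98e-05, adjusted p = 0.282 with an estimated correlation). Cd74 stood at 2933 ± 1051 against 1046 ± 219 CPM. Transitional alveolar epithelium markers rose (7 of 15 adjusted over the list alone, camera adjusted p = 1.08e-06) and so did TGF-beta signalling (5 of 19, camera adjusted p = 1.12e-06), each with an adjusted p = 0.203 with an estimated correlation. Itgb6, an integrin chain that activates TGF-beta, had a log2 fold change of 2.38 (SE 0.31, adjusted p = 0.111), and Lcn2 of 1.98 (SE 0.46).

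Smooth muscle and contractile genes fell (7 of 12 adjusted over the list alone, median log2 fold change -0.99, camera adjusted p = 1.06e-06, adjusted p = 0.113 with an estimated correlation). Their sum did not fall in every section, at 4354, 2118 and 2147 CPM in the day 14 sections against 3394 and 4146 CPM at day 0. These sums lack the TMM scaling of the list test. The TMM factor was 1.12 for day 14 replicate 1 and 0.958 and 0.899 for the day 0 sections. With this scaling day 14 replicate 1 lay between the day 0 sections. Myh11, smooth muscle myosin, had a log2 fold change of -1.85 (SE 0.30). Alveolar fibroblast markers fell (5 of 9 adjusted over the list alone, camera adjusted p = 2.66e-05, adjusted p = 0.203 with an estimated correlation), with Inmt at 486 ± 137 against 3145 ± 785 CPM. Club and secretory genes fell (5 of 8 adjusted over the list alone, camera adjusted p = 0.000205, adjusted p = 0.203 with an estimated correlation), with Cyp2f2, a club cell cytochrome P450, at 1137 ± 226 against 4353 ± 1644 CPM. Alveolar type 2 markers fell (3 of 11 adjusted over the list alone, camera adjusted p = 0.000891, adjusted p = 0.203 with an estimated correlation), with the surfactant protein gene Sftpa1 at 1199 ± 167 against 3045 ± 54.2 CPM, and this call was lost without day 0 replicate 1 (camera adjusted p = 0.0957). Sftpc had a log2 fold change of -0.81 (SE 0.39, adjusted p = 0.452) and the alveolar type 1 gene Ager of -0.12 (SE 0.38, adjusted p = 0.941).

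Lists that can follow tissue handling and RNA quality were also called lower at day 14. These were immediate early and heat shock genes (2 of 12 adjusted over the list alone, median -0.56, camera adjusted p = 0.0497, adjusted p = 0.546 with an estimated correlation) and mitochondrially encoded genes (0 of 12, median -0.23, camera adjusted p = 0.0344, adjusted p = 0.622 with an estimated correlation). The mitochondrially encoded sum stood at 32525 CPM in day 14 replicate 1, the highest of all sections, and at 12295 and 12735 CPM in replicates 2 and 3. At day 0 it stood at 17258 and 20128 CPM. The means of these sums, 19185 CPM at day 14 and 18693 CPM at day 0, lack the TMM scaling that the list test used. TMM factors were 1.12, 1.08 and 1.19 at day 14 and 0.958 and 0.899 at day 0, which lowers the day 14 sums against day 0. The order of the unscaled means therefore says nothing against the call. The first call was lost without day 0 replicate 2 (camera adjusted p = 0.959, median 0.37), day 14 replicate 3 (0.288), day 35 replicate 2 (0.0586) or day 35 replicate 3 (0.0543), and the second without day 0 replicate 2 (0.211), day 14 replicate 2 (0.349) or day 14 replicate 3 (0.46). In all, 26 of 43 lists were called, 16 higher and 10 lower, 0 of them with an estimated correlation and 2 by fry. Whichever section was left out, 15 of the 26 kept their call and direction, and 21 did without both sections rich in squamous and skeletal muscle markers.

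**Figure D1:**
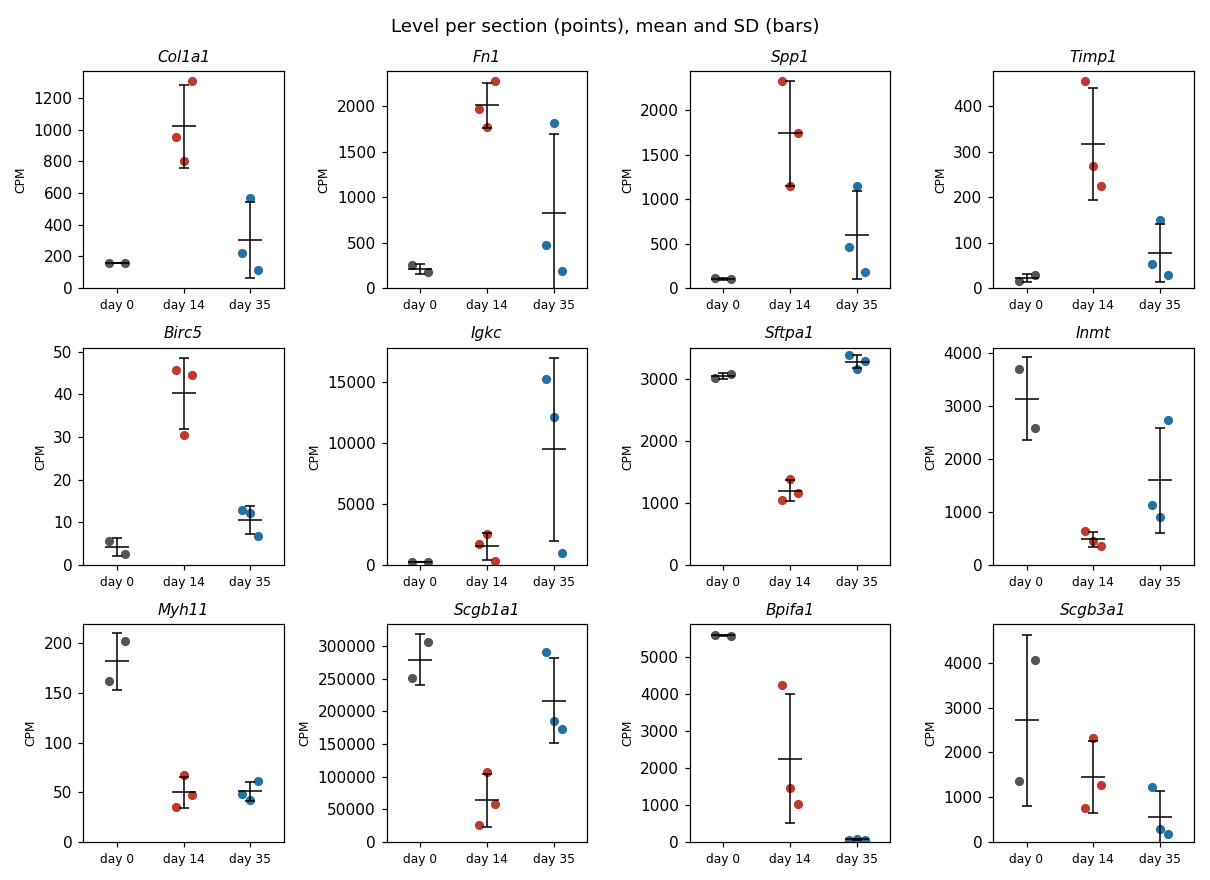
Level of 12 genes in CPM (vertical axes, linear, from 0) for each section (points) at day 0, day 14 and day 35, with the mean and SD as bars. Bpifa1 lies at 59.7 to 69.4 CPM in the 3 day 35 sections, and the Spp1 level at day 14 lies above that of both day 0 sections in each section.

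The comparison of day 35 with day 0 asked what remained different at the late time. Bpifa1, a secreted protein of the upper and large airways (chromosome 2, 154142880 to 154149217), fell to 63.7 ± 5.08 CPM (SD, n = 3) from 5589 and 5566 CPM in the day 0 sections (n = 2), a log2 fold change of -6.45 (SE 0.59, adjusted p = 0.00454) and lower in all 3 sections. It was the 1 gene of 13260 that edgeR called, and 867 genes had an unadjusted p under 0.05; DESeq2 called 62. Groups did not overlap for 22.1% of genes, against 20% by chance. The Bpifa1 call was lost without day 35 replicate 1 (log2 fold change -6.405, SE 0.75, adjusted p = 0.0695) and without day 35 replicate 2 (-6.52, SE 0.70, adjusted p = 0.0607), and the count rose to 10 without day 14 replicate 1 and to 7 without day 35 replicate 3. Bpifa1 passed with the file label digit as a term (1 gene).

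Smooth muscle and contractile genes fell at day 35 (11 of 12 adjusted over the list alone, median log2 fold change -1.29, camera adjusted p = 1.19e-11). This was the 1 list called with an estimated correlation (adjusted p = 0.0253 with an estimated correlation), and that call was lost when any single section was left out. Myh11 stood at 50.8 ± 9.82 against 182 ± 28.5 CPM and Cnn1, calponin, at 87.7 ± 56.3 against 350 ± 75.5 CPM. Beside it, cardiac muscle markers fell (0 of 10 adjusted over the list alone, camera adjusted p = 7.54e-08, adjusted p = 0.305 with an estimated correlation), and summed to 3570 ± 1071 CPM at day 0 and 688 ± 918 CPM at day 35. The proximal airway list, chosen after the results were seen, summed to 2075 and 5416 CPM at day 0. In the day 35 sections it summed to 1395, 337 and 449 CPM. Whether the sections hold unlike amounts of large airway, vessel or heart tissue was not tested for the smooth muscle list. Club and secretory genes fell (3 of 8 adjusted over the list alone and 1, Bpifa1, over all genes, camera adjusted p = 1.03e-06, adjusted p = 0.302 with an estimated correlation). The antibacterial lectin gene Reg3g stood at 32.4 ± 22.1 against 325 ± 41.7 CPM, while Scgb1a1 had a log2 fold change of -0.37 (SE 0.53, adjusted p = 0.933).

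Plasma cell genes, which encode antibody chains, rose (8 of 10 adjusted over the list alone, median 4.76, camera adjusted p = 5.94e-08, adjusted p = 0.305 with an estimated correlation). Igkc, the kappa light chain constant region (chromosome 6, 70726435 to 70726754), stood at 15263, 12162 and 980 CPM in the day 35 sections against 227 and 216 CPM at day 0. Erythroid genes rose as well (5 of 5 adjusted over the list alone, camera adjusted p = 0.000599, adjusted p = 0.305 with an estimated correlation) and summed to 11875 ± 8668 against 1545 ± 827 CPM. By section the sums were 2224, 18997 and 14404 CPM at day 35 against 2129 and 960 CPM at day 0, so day 35 replicate 1 lay near day 0 replicate 1. Monocyte-derived macrophage markers rose (10 of 12 adjusted over the list alone, median 2.31, camera adjusted p = 1.64e-08, adjusted p = 0.302 with an estimated correlation), with Trem2 at 34.5, 131 and 21.0 CPM in the day 35 sections against 6.14 and 4.88 CPM at day 0. The list summed to 3021, 8973 and 1634 CPM in the day 35 sections against 1111 and 1175 CPM, and without day 35 replicate 2 Trem2 had a log2 fold change of 2.33 (3.47 with it). MHC class II genes rose (6 of 8 adjusted over the list alone, median 1.49, camera adjusted p = 6.41e-08, adjusted p = 0.302 with an estimated correlation), and complement genes rose (3 of 10, camera adjusted p = 5.02e-06, adjusted p = 0.302 with an estimated correlation). C4b, a complement component, stood at 363 ± 102 against 136 ± 45.5 CPM.

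Fibrillar collagens and interstitial matrix were not called at day 35 against day 0 (0 of 23 adjusted over the list alone, median 0.62, camera adjusted p = 0.0698). Col1a1 stood at 222, 571 and 112 CPM in the 3 sections against 160 ± 0.537 CPM (log2 fold change 0.92, SE 0.56, adjusted p = 0.805), and Col3a1 had a log2 fold change of 0.34 (SE 0.48), which became -0.35 without day 35 replicate 2. Sftpc, with 0.37 (SE 0.40), and Cthrc1, with 1.37 (SE 0.98), also changed sign in some fits. Immediate early and heat shock genes were called lower (1 of 12 adjusted over the list alone, median -0.68, camera adjusted p = 0.00034, adjusted p = 0.305 with an estimated correlation), and mitochondrially encoded genes as well (0 of 12, median -0.49, camera adjusted p = 0.0173, adjusted p = 0.653 with an estimated correlation). Both calls were lost without day 0 replicate 2 (camera adjusted p = 0.371 and 0.247), and the second also without day 35 replicate 1 (0.117) or day 35 replicate 2 (0.0979). The mitochondrially encoded sum stood at 11176, 10673 and 20247 CPM in the day 35 sections and at 17258 and 20128 CPM at day 0, without TMM scaling. TMM factors were 1.01 for day 35 replicate 3 and 0.958 and 0.899 for the day 0 sections. With this scaling day 35 replicate 3 lay between the day 0 sections. In all, 27 of 43 lists were called, 17 higher and 10 lower, and 16 of them whichever section was left out.

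**Figure D2:**
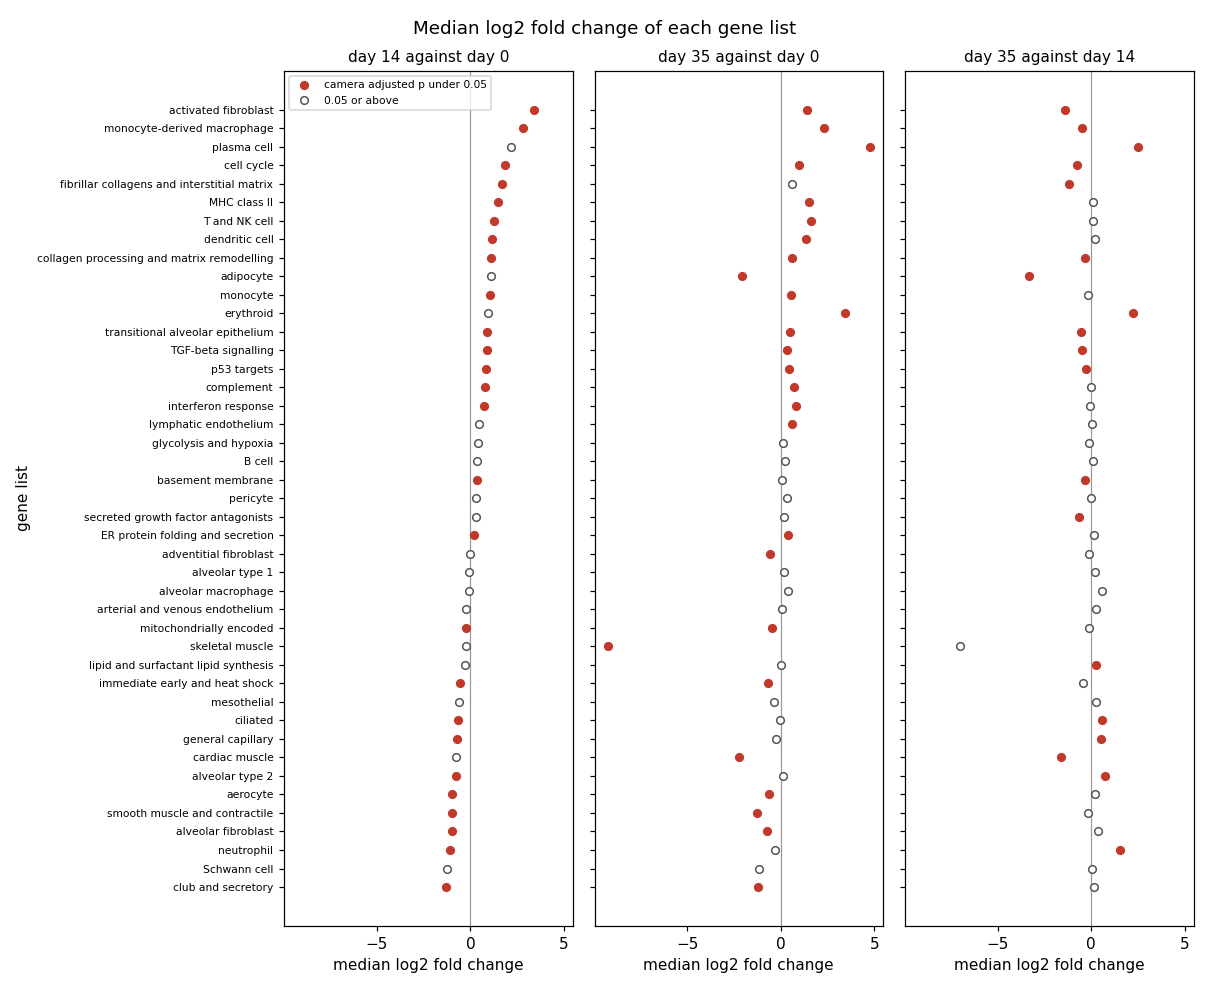
Median log2 fold change (horizontal axes) of the 43 gene lists (vertical axis, ordered by day 14 against day 0) in the 3 comparisons of days, with filled points for lists called by camera at an adjusted p under 0.05. Fibrillar collagens lie at 1.71, 0.62 and -1.19 from left to right, and plasma cell genes at 4.76 in the middle panel.

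Between day 14 and day 35, matrix and proliferation lists fell and alveolar type 2 markers rose. Fibrillar collagens and interstitial matrix fell (12 of 23 adjusted over the list alone, median log2 fold change -1.19, camera adjusted p = 7.28e-16, adjusted p = 0.475 with an estimated correlation). Tnc stood at 41.9 ± 35.9 CPM (SD, n = 3) at day 35 against 226 ± 40.4 (n = 3) at day 14, and lumican, Lum, at 20.7 ± 6.16 against 101 ± 55.7 CPM. Cell cycle genes fell (7 of 17 adjusted over the list alone, camera adjusted p = 1.92e-08, adjusted p = 0.441 with an estimated correlation), with Birc5 at 10.6 ± 3.27 against 40.2 ± 8.38 CPM. Alveolar type 2 markers rose (6 of 11 adjusted over the list alone, median 0.76, camera adjusted p = 5.06e-07, adjusted p = 0.441 with an estimated correlation). Sftpa1 stood at 3280 ± 107 against 1199 ± 167 CPM and Sftpc at 19708 ± 6118 against 8689 ± 451 CPM.

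Activated fibroblast markers fell (1 of 7 adjusted over the list alone, camera adjusted p = 5.48e-05, adjusted p = 0.508 with an estimated correlation), and Cthrc1 had a log2 fold change of -2.05 (SE 0.75). Neutrophil genes rose (4 of 7 adjusted over the list alone, camera adjusted p = 0.000427, adjusted p = 0.508 with an estimated correlation), with the calprotectin gene S100a8 at 133 ± 72.6 against 25.6 ± 5.26 CPM. The neutrophil list summed to 151, 425 and 358 CPM in the day 35 sections. Its mean of 311 CPM at day 35 was not above the 320 CPM of day 0, where the sections gave 140 and 500 CPM. Plasma cell genes rose (4 of 10 adjusted over the list alone, camera adjusted p = 7.65e-05, adjusted p = 0.508 with an estimated correlation), and Igha had a log2 fold change of 3.69 (SE 1.07) with overlapping sections; the list was not called without day 35 replicate 2 (camera adjusted p = 0.0776). Bpifa1 was the 1 gene called by edgeR (log2 fold change -5.13, SE 0.54, adjusted p = 0.0191, lower in all 3 sections); 842 genes had an unadjusted p under 0.05, and DESeq2 called 47. The Bpifa1 call was lost without day 0 replicate 1, day 0 replicate 2, or any day 35 section (0 genes each), where its log2 fold change stayed between -5.09 and -5.20. It was also lost with the replicate block (-4.90, SE 0.52, adjusted p = 0.1225, 0 genes), whose terms leave fewer degrees of freedom, and with the file label digit as a term (-5.12, SE 1.07, adjusted p = 1, 0 genes), where the fold hardly moved and the SE rose. All day 14 sections carry the digit 1 and all day 35 sections the digit 2, so this comparison has no value within a digit. In all, 19 of 43 lists were called, 7 higher and 12 lower, and 7 whichever section was left out. Groups did not overlap for 11.7% of genes, against 10% by chance.

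Log2 fold changes at day 14 and at day 35, both against day 0, had a Pearson correlation of 0.543 across genes, which are not independent replicates, and a covariance of 0.449. Unchanged groups simulated against the same day 0 sections gave 0.609 and 0.222. The edgeR calls of the 2 comparisons shared 0 genes, against 0 for independent lists and at most 1 in the simulations. Since 0 genes were called at day 14 against day 0, the first 2 of these values were fixed and say nothing about sharing. DESeq2 calls shared 41. The day 0 sections are too few to split, so part of the covariance may come from them.

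Collagen transcripts were then followed across the tissue. The share of collagen-high neighbourhoods was 3.46% and 3.23% in the day 0 sections, 57.9%, 50.5% and 75.6% at day 14, and 4.95%, 21.9% and 2.03% at day 35. The means were 3.35 ± 0.166% (SD, n = 2), 61.4 ± 12.9% (n = 3) and 9.62 ± 10.7% (n = 3). The threshold was set on the day 0 sections, so their low share is partly fixed by construction. Their SD is therefore no independent measure of spread, and the tests against day 0 share this limit. Day 14 exceeded day 0 by 58.0 percentage points (exact permutation p = 0.1) and day 35 differed from day 14 by -51.8 points (exact permutation p = 0.1), where 0.1 is the smallest p these numbers of sections allow. Day 35 exceeded day 0 by 6.27 points (exact permutation p = 0.7), and by 0.141 points without day 35 replicate 2. Neighbourhoods under 1000 UMIs were left out, 794 of them in day 14 replicate 1 and 340 in day 35 replicate 2. Without thinning the means were 4.89%, 90.7% and 19.8%. With single spots thinned to 200 UMIs they were 1.03%, 15.5% and 1.81%. With Scgb1a1 left out of the total they were 1.92%, 46.6% and 4.83%, and day 35 exceeded day 0 by 2.91 points.

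**Figure D3:**
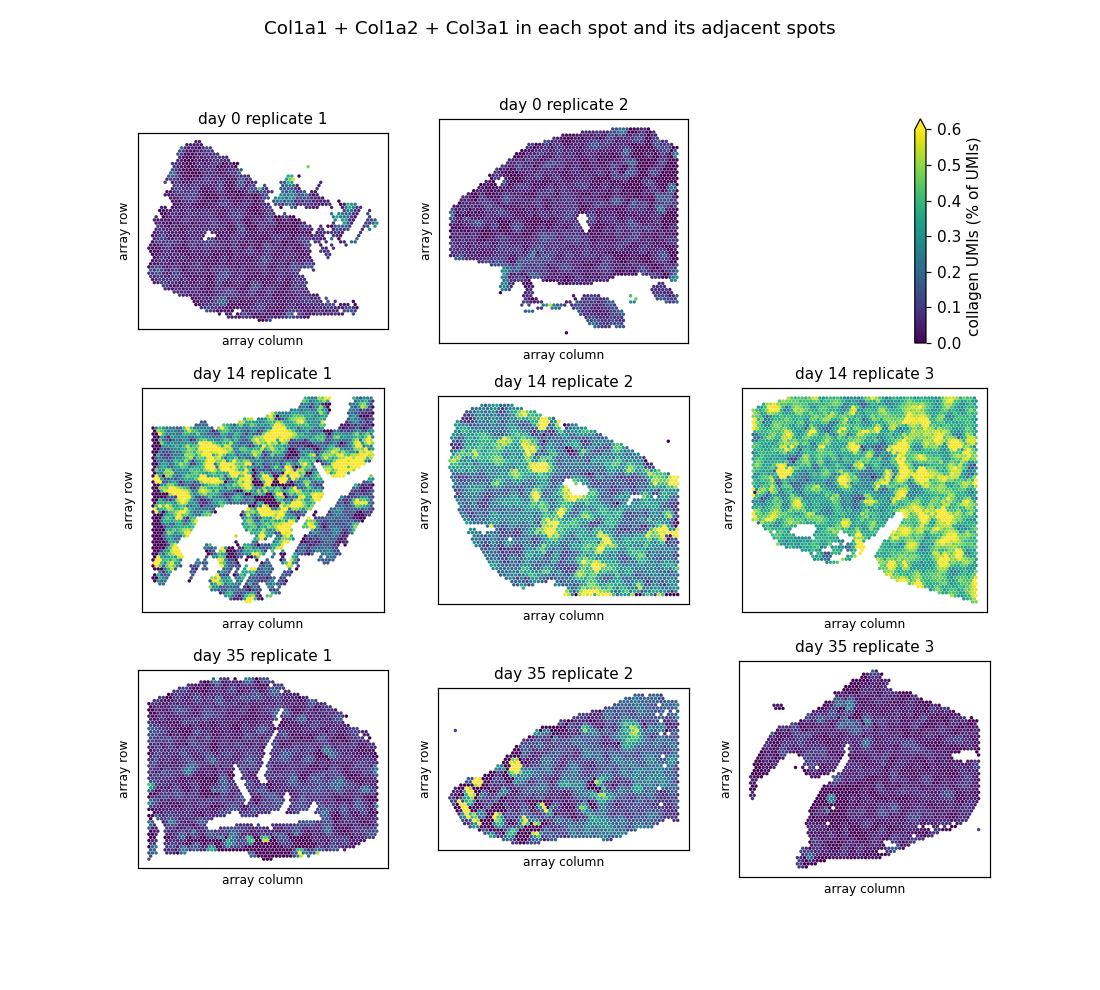
Col1a1, Col1a2 and Col3a1 UMIs in percent of the UMIs of each spot and its adjacent spots (colour, from 0 to 0.6 and above) at the array position of the spot, for the 8 sections. Day 14 sections are high over most of the tissue, and in day 35 replicate 2 the high spots lie in patches. Adjacent spots share UMIs in this score, so patches arise in part by construction. Clustering of the high spots was not tested.

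**Figure D4:**
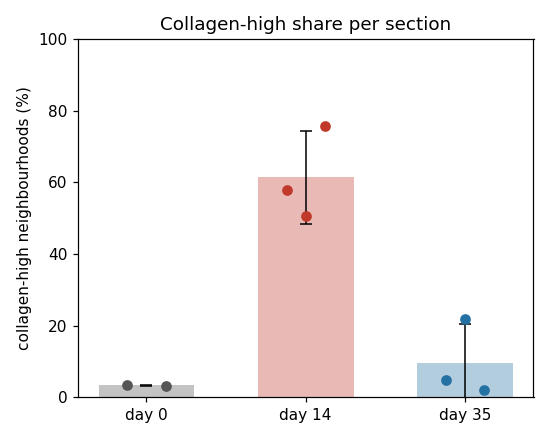
Share of collagen-high neighbourhoods in percent (vertical axis) per section (points), with the mean (columns) and SD (bars) at day 0, day 14 and day 35. The day 14 sections lie between 50.5% and 75.6%.

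Within sections, collagen-high spots were compared with collagen-low spots to find which transcripts lie with collagen. At day 0, 53 of 9699 genes were higher in collagen-high spots and 0 were lower. Tagln, a smooth muscle actin-binding protein, was higher by 1.84 on the log2 scale (SE 0.21, adjusted p = 3.82e-09) and Dcn, the small proteoglycan decorin, by 1.51 (SE 0.24, adjusted p = 5.2e-05), each in both sections. Smooth muscle and contractile genes were higher (12 of 12 adjusted over the list alone, camera adjusted p = 3.66e-09, adjusted p = 0.511 with an estimated correlation). Skeletal muscle genes moved with them (5 of 5 adjusted over the list alone, camera adjusted p = 0.00949, adjusted p = 0.692 with an estimated correlation), and so did Ttn (1.33, SE 0.23) and Myl1 (1.16, SE 0.21), striated muscle genes outside that list, of which neither passed without the spots rich in squamous and skeletal muscle markers (0.71, adjusted p = 0.738, and 0.11, adjusted p = 0.991). Cardiac muscle genes did too (8 of 10 adjusted over the list alone, camera adjusted p = 1.28e-05, adjusted p = 0.692 with an estimated correlation), with Tnni3 at 0.83 (adjusted p = 0.00269) and at 0.96 (adjusted p = 0.000348) without those spots. Mitochondrially encoded genes were also higher (9 of 12 adjusted over the list alone, camera adjusted p = 6.95e-06, adjusted p = 0.692 with an estimated correlation). Without the marker-rich spots 19 genes were called, 16 of them among the 53, and 14 genes were called without day 0 replicate 2. DESeq2 called 0, with 61 genes at an unadjusted p under 0.05. Of 42 lists 9 were called, and 5 without day 0 replicate 1, where smooth and cardiac muscle genes each had a camera adjusted p = 0.0699; skeletal muscle genes had 0.42 without day 0 replicate 2.

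At day 14, 15 genes were higher and 137 lower in collagen-high spots. Fn1 was higher by 0.59 (SE 0.11, adjusted p = 0.000366), the macrophage elastase gene Mmp12 by 0.66 (SE 0.15, adjusted p = 0.00319), Thbs1 by 0.58 (SE 0.13) and Timp1 by 0.53 (SE 0.12), each in 3 of 3 sections. The antibody genes Jchain and Ighm had 0.91 (SE 0.20) and 0.66 (SE 0.16), and both calls were lost without the marker-rich spots (0.65, adjusted p = 0.14, and 0.31, adjusted p = 0.74). Fibrillar collagens and interstitial matrix, without the scoring genes, were higher (12 of 20 adjusted over the list alone, median 0.39, camera adjusted p = 5.07e-09, adjusted p = 0.315 with an estimated correlation). Club and secretory genes were lower (8 of 8 adjusted over the list alone, median -1.01, camera adjusted p = 1.82e-10, adjusted p = 0.315 with an estimated correlation), among them Scgb3a2 at -1.47 (SE 0.16). The score is a share of all UMIs, so a spot rich in Scgb1a1 and other secretory transcripts scores lower through its total. The classes were not run with Scgb1a1 left out of the total. Ciliated genes were lower (7 of 9 adjusted over the list alone, camera adjusted p = 7.83e-06, adjusted p = 0.315 with an estimated correlation), with Tmem212 at -1.08 (SE 0.20). Calml3, of squamous epithelium, had -2.44 (SE 0.36) and Neb, of striated muscle, -2.83 (SE 0.65), and without the marker-rich spots neither passed (-1.36, adjusted p = 0.207, and -0.92, adjusted p = 0.913). Mitochondrially encoded genes were lower (10 of 12 adjusted over the list alone, camera adjusted p = 6.67e-09, adjusted p = 0.353 with an estimated correlation), and so were cardiac muscle genes (10 of 10, camera adjusted p = 6.13e-05, adjusted p = 0.426 with an estimated correlation). Without the marker-rich spots 85 genes were called, 73 of them among the 152, and 58 were called without day 14 replicate 1. DESeq2 called 21. Of 42 lists 14 were called, 9 of them whichever section was left out.

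At day 35 the 1 gene called was Scgb3a2, a secretory protein of distal airways, lower in collagen-high spots by -0.84 (SE 0.16, adjusted p = 0.0103) in 3 of 3 sections. With 10% of spots per class its value was 0.17, the other direction, with 0 genes called, and 0 were called with the score of the adjacent spots only. Club and secretory genes were lower (5 of 8 adjusted over the list alone, camera adjusted p = 0.000474, adjusted p = 0.89 with an estimated correlation). For these genes and Scgb3a2 the limit given for day 14 holds too, since secretory UMIs enter the total of the score. Of 42 lists 6 were called, 2 without day 35 replicate 1 and 0 without day 35 replicate 2. DESeq2 called 0 genes (42 at an unadjusted p under 0.05), and edgeR called 0 without day 35 replicate 2, 4 without day 0 replicate 1, and 3 each without day 14 replicate 1 or day 35 replicate 3.

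The class effect changed between day 0 and day 14 for 125 genes, all lower at day 14, among them Tagln by -1.39 (adjusted p = 0.000657) and Dcn by -1.43 (adjusted p = 0.00132). Among the 125 were 9 cardiac muscle and 10 mitochondrially encoded genes, such as Tnni3 (-1.60, adjusted p = 1.26e-06) and mt-Co1 (-1.39, adjusted p = 1.32e-07). Without the marker-rich spots 51 genes were called, 49 of them among the 125, and Tagln had -1.58 (adjusted p = 2.79e-05). The count was 56 without day 0 replicate 2 and 43 without day 14 replicate 1. Between day 0 and day 35 the interaction called 0 genes in edgeR, with 476 at an unadjusted p under 0.05, and 0 in DESeq2 (56 unadjusted). Left-out sections moved this count to 13 (day 14 replicate 1), 4 (day 0 replicate 2), 3 (day 0 replicate 1) and 2 (day 35 replicate 3). Between day 14 and day 35 it called 1 gene, the fast skeletal troponin gene Tnni2 (3.89, adjusted p = 0.00598). DESeq2 called 0 (26 unadjusted), and edgeR 0 without day 35 replicate 1 or day 35 replicate 3, 5 without day 35 replicate 2, and 2 each without day 14 replicate 1 or day 14 replicate 3.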

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

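The tests of UMI depth, of the amount of airway tissue and of a batch by file label digit, the test of single day 35 sections against day 0, the squamous and proximal airway lists, the marker-rich spots, and 2 of the 3 position correlations were chosen after the results were seen.

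The difference between collagen-high and collagen-low spots changed between day 0 and day 14 for 125 genes and between day 14 and day 35 for 1 gene by the interaction test, which is why these results stand here. The classes are relative to each section and span unlike collagen levels between days. Between day 0 and day 14 the log2 change was -1.39 for Tagln, -1.43 for Dcn, -1.43 for Scgb3a2, -2.97 for Car3, -1.60 for the cardiac gene Tnni3 and -1.39 for the mitochondrially encoded mt-Co1, and these 6 also passed without the marker-rich spots (-1.58, -1.13, -1.65, -2.70, -1.90 and -1.24). Leaving out the marker-rich spots removed only 34.0% and 55.2% of the marker UMIs in the 2 sections. Passing therefore does not exclude a part for the source of these transcripts. The muscle genes Myl1 (-2.98), Neb (-4.53), Ttn (-3.01), Tnni2 (-3.13) and Smpx (-3.10), with Eef1a2 (-3.11), Aldh3a1 (-2.51) and Calml3 (-3.01), did not pass without those spots. Between day 14 and day 35 Tnni2 changed by 3.89, and by 1.71 (adjusted p = 1) without those spots. For the count of 1 gene, other splits of the 6 sections of days 14 and 35 gave up to 11 genes, and 8 of the 10 splits gave at least as many; 10 splits are too few for a share under 0.05. For the comparison of those days itself, the real split gave 1 gene and the highest other split 0 (1 of 10 splits), and the real split called 19 lists and the split of day 14 replicate 1 with day 35 replicates 1 and 3 against the rest 20 (2 of 10 splits).

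Squamous and skeletal muscle transcripts in day 0 replicate 2 and day 14 replicate 1 may come from another tissue in the section or from reads carried over between the libraries, and no biological explanation was tested. Alveolar transcripts per UMI in marker-rich spots were 0.626 (day 0 replicate 2) and 0.433 (day 14 replicate 1) times their level in other spots. A second tissue was set beforehand to need at most 0.5 in both sections, which only day 14 replicate 1 met, and at least 0.8 in both would have argued against it, so it stays open. Squamous UMIs at the 2198 shared array positions had a Spearman correlation of 0.267 between the sections, between the bounds of 0.2 and 0.5 set beforehand, so carry-over stays open too. That is the version fixed beforehand, and 3 were computed: with skeletal muscle UMIs added the correlation was 0.321, and for the squamous share of UMIs 0.014. Total UMIs at these positions correlated at 0.459.

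Collagen differed widely between the day 35 sections, with Col1a1 at 222, 571 and 112 CPM. Few UMIs per spot in replicate 3 are argued against by its median of 593.5 UMIs, above the 511 of replicate 2 (at equal UMIs the collagen-high share of replicate 2 was 10.8 times that of replicate 3). For airway and vessel walls as the place of collagen in replicate 2, the log2 ratio of smooth muscle transcripts between its collagen-high and collagen-low spots was 0.0913. This was below the bound of 0.2 set beforehand to argue against such walls. Secretory UMIs enter the total of the score, however, and move airway spots towards the collagen-low class. Club and secretory and ciliated transcripts had log2 ratios of -0.624 and -0.618 in replicate 2, so the smooth muscle ratio cannot decide. A wrong label on replicate 3 stays open: over 561 genes that part replicates 1 and 2 from day 0 its median position was 0.311 from day 0 (0) to those replicates (1), between the bounds of 0.25 and 0.5. These genes were chosen on replicates 1 and 2, which can draw any other section below 1. The day 14 sections lay at 0.55, 0.94 and 0.87. The log2 CPM of replicate 3 correlated at 0.929 and 0.872 with the day 0 sections and at 0.912 and 0.88 with the other day 35 sections. Against such a label stand its Bpifa1 at 62.1 CPM (5589 and 5566 at day 0) and Reg3g at 8.80 CPM (295 and 354), airway genes that may also follow the level of the airway tree in a section; edgeR fits of single day 35 sections against day 0 do not decide, with 0 genes for replicate 3, 0 for replicate 1 and 41 for replicate 2 (Bpifa1 adjusted p = 0.376, 1 and 0.0414). A difference between animals in the course of injury is an untested explanation that could also give this spread.

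Bpifa1 was lower at day 35 than at day 0. Less airway tissue is argued against, since the other 16 club, secretory and ciliated genes had a median log2 fold change of -0.27, and a batch by file label digit is argued against by a ratio of 0.996 between the day 0 sections, which carry different digits. Another level of the airway tree in the sections stays open: the proximal airway list, which holds 3 genes of the club and secretory list, had a median of -1.92, short of the -2 set beforehand, with Bpifb1 at -4.13 (SE 0.63) and Muc5ac at -0.06 (SE 1.11). A lasting change of the airway epithelium after injury may also explain it and was not tested.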

How the results depend on the processing

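The fits without marker-rich spots, without both sections that hold them and without Scgb1a1 were chosen after the results were seen. Over the summary results 204 values under alternatives were counted as kept (for counts, within 1.5 times of the reported one) and 90 as moved. The 204 include collagen-high shares that changed by more. With single spots thinned to 200 UMIs, day 14 exceeded day 0 by 14.4 points, against 58.0 as reported. For named genes 2120 kept direction and side of the threshold, 199 passed only under the alternative, 150 passed only as reported and 8 reversed. The cause was not tested except where said.

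Genes changed from day 0 to day 14 numbered 266 with DESeq2, 315 with no filter on low counts and 72 with only the 2 groups in the fit (0 as reported), and ranged from 0 to 83 with a section left out. From day 0 to day 35 they numbered 62, 250 and 5, with 2 after thinning to the smallest section total and 3 without both sections (1 as reported), and ranged from 0 to 10. From day 14 to day 35 they numbered 47 with DESeq2, 173 with no filter, 0 with the file label digit, 2 after thinning and 2 without both sections (1 as reported), and ranged from 0 to 1. Genes called at both days numbered 41 with DESeq2 and 87 with no filter (0 as reported), and ranged from 0 to 4.

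With the replicate number as a block, the counts were 0, 4 and 0 genes and 27, 26 and 18 lists, and the smallest adjusted p at day 14 was 0.0547. Whether the numbers pair the sections stays open. Deviations of sections with the same number correlated between -0.317 and 0.084, and those with different numbers between -0.267 and 0.317. The deviations of the 2 day 0 sections mirror each other, so these values are not independent and cannot decide it.

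Lists called fell to 0, 1 and 0 with an estimated correlation and to 2, 1 and 0 with fry, and with a section left out ranged from 22 to 30, 23 to 30 and 16 to 20. For the collagen classes lists fell to 0, 0 and 0 with an estimated correlation, to 1 at day 35 with the adjacent spots only, and ranged from 5 to 9, 14 to 17 and 0 to 6.

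Genes differing between the classes at day 0 (53) numbered 0 with DESeq2, 24 with the adjacent spots only, 21 with the spot alone, 24 without both sections and 19 without marker-rich spots, and ranged from 14 to 68. At day 14 (152) they numbered 21 with DESeq2, 41 with the spot alone, 79 with 10% of spots per class, 63 without both sections and 85 without marker-rich spots, and ranged from 58 to 176. At day 35 (1) they numbered 0 with DESeq2, 5 with no filter, 0 with the adjacent spots only, 2 with the spot alone, 3 with spots of at least 200 UMIs, 0 with 10% of spots per class, 3 without both sections and 2 without marker-rich spots, and ranged from 0 to 4. The change between day 0 and day 14 (125) numbered 22 with DESeq2, 46 with the spot alone, 33 without both sections and 51 without marker-rich spots, and ranged from 43 to 132. Between day 0 and day 35 (0) it numbered 10 with no filter, 11 without both sections and 1 without marker-rich spots, and ranged from 0 to 13. Between day 14 and day 35 (1) it numbered 0 with DESeq2, 2 with no filter, 2 with the adjacent spots only, 0 with the spot alone, 2 with spots of at least 200 UMIs, 4 with 10% of spots per class and 2 without both sections, and ranged from 0 to 5.

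Reversed log2 values, with the range over left-out sections, were Ager, day 14 against day 0, without day 0 replicate 1 (-0.41 to 0.23), Col3a1, day 35 against day 0, and Cthrc1, day 35 against day 0, without day 35 replicate 2 (-0.35 to 0.68 and -0.60 to 2.08), and Sftpc, day 35 against day 0, without day 0 replicate 2 (-0.0302 to 0.94) and without both sections (-0.031). In the classes they were Tnni2, high against low, day 0, without marker-rich spots (-0.0064), Fbln5, high against low, day 14, with the spot alone (-0.0226) and Scgb3a2, high against low, day 35, with 10% of spots per class (0.17). The collagen-high shares kept their direction in every setting, and the 90th percentile gave the same threshold as the 95th, so that setting tests nothing. Depth limits the classes: 10% of spots per class left 4701 genes to test against 9699.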

Other observations

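The tests without both sections rich in squamous and skeletal muscle markers were chosen after the results were seen, and the lists below were fixed before.

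Several immune and stress lists that the comparisons above leave out were also called by camera at day 14 against day 0. Interferon response genes rose (3 of 18 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.246 with an estimated correlation). Targets of p53 rose (3 of 14 adjusted over the list alone, camera adjusted p = 1.59e-05, adjusted p = 0.203 with an estimated correlation), and the cell cycle inhibitor gene Cdkn1a stood at 187 ± 18.7 against 42.4 ± 31.0 CPM. Neutrophil genes fell (3 of 7 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.263 with an estimated correlation), with the receptor gene Csf3r at 6.29 ± 1.51 against 31.5 ± 17.0 CPM, and this call was lost without both sections and without day 0 replicate 2 (camera adjusted p = 0.196). Aerocyte markers, of the capillary cells that take part in gas exchange, fell (4 of 7 adjusted over the list alone, camera adjusted p = 0.000861, adjusted p = 0.203 with an estimated correlation), a call lost without day 0 replicate 1 (camera adjusted p = 0.0731).

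At day 35 against day 0, interferon response genes rose (3 of 18 adjusted over the list alone, camera adjusted p = 3.75e-07, adjusted p = 0.302 with an estimated correlation), with Rsad2 at 26.3 ± 9.61 against 5.87 ± 3.28 CPM. Dendritic cell markers rose (4 of 7 adjusted over the list alone, camera adjusted p = 8.75e-05, adjusted p = 0.302 with an estimated correlation). Cell cycle genes rose (0 of 17 adjusted over the list alone, median 0.98, camera adjusted p = 1.03e-06, adjusted p = 0.302 with an estimated correlation) and summed to 270 ± 26.8 CPM against 190 ± 32.1 CPM at day 0. The B cell list summed to 2459, 6217 and 461 CPM in the day 35 sections against 330 and 242 CPM at day 0, and was not called (camera adjusted p = 0.523).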
